A study of Arabidopsis thaliana with 12 samples.

How the data were processed

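Leaf RNA of Arabidopsis thaliana was measured on Affymetrix ATH1 arrays, on which short probes are grouped into probe sets, most of them read as 1 transcript. The series holds 12 arrays, 3 in each of 4 groups: wild type Col-0 and the des1-1 insertion line, each watered with plain water or with a sodium sulfide solution. Groups and replicate numbers were taken from the sample labels, and the series' design text calls the replicates biological.

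The deposited table gives log2 expression values made by robust multi-array average (RMA) in the R package affy, per the submitters' processing notes, with versions not stated there. RMA corrects background, brings the arrays processed together to 1 distribution and summarises the probes of each set. The notes do not say whether all 12 arrays were processed together. Where they were, a shift shared by most transcripts of a sample would be removed before deposit. Differences of dim transcripts are compressed in either case. The values were used as deposited. Array medians lay between 5.71 and 5.80. Arrays give no read depth, and the number of arrays limits the precision.

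The file held 22810 probe sets, of which 64 were control probe sets and 22746 were tested. Of those tested, 13513 had 1 gene listed in the platform annotation used here, 503 had several and 8730 had none listed; 13436 of the first were matched to 1 locus in a gene table of assembly TAIR10.1, used for names only. A probe set without a listed gene is unnamed here, not without a gene. No genome build applies to the values, and no coordinates are given. The transcripts of DES1 itself and of its relatives CYSD1 and CYSD2 are not analysed here, because no probe set used here is paired with them, so the labels of the insertion line were not checked against its own gene.

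One linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, neither trend nor robust) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over the 22746 probe sets of each comparison, with a threshold of 0.05. The comparisons were des1 against wild type under water and under sulfide, sulfide against water in each genotype, the interaction (the genotype difference under sulfide minus that under water), and treated des1 against untreated wild type. Errors beside log2 differences are limma standard errors (SE), and all adjusted p-values of single genes come from limma. Overlaps of calls were tested with Fisher's exact test, two-sided.

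Gene lists for sulfur, stress, hormone, leaf age and cell type themes were fixed by locus, 28 lists with 507 entries in all. Of these entries 71 had a probe set and were used, 3 were left out because the annotated symbol differed from the one fixed, and 433 had no probe set listed. Measured genes of a list are those used here. The arrays may carry others among the probe sets without a listed gene. The 8 lists with at least 3 measured members were tested with limma's camera (preset correlation 0.01, adjusted over lists), namely autophagy, leaf senescence, flavonoid and anthocyanin synthesis, photosynthesis, abscisic acid and osmotic response, antioxidants and glutathione, glucosinolates, and carbon starvation. Camera with an estimated correlation and fry were run beside it. Genes of the remaining lists are reported singly. Families of genes by symbol, and the genes of both organelle genomes, were added after the data were seen.

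Genes were named by a fixed rule: among probe sets of exactly 1 gene that passed the test with no overlap between the 3 values of each group, the 10 largest rises and the 10 largest falls of each comparison (5 and 5 for the interaction), and up to 4 members of a list by size of change. The groups, comparisons, lists, this rule and the alternatives were set before the data were examined. Genes outside the rule are named as chosen after their values were seen.

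The alternatives were quantile normalization again, centring of arrays on their medians, leaving out probe sets whose mean lay below the 40th percentile, a trended robust variance model, array weights, a fit to the compared arrays alone, the replicate number as a block, a 2-fold minimum, probe sets of 1 gene only, and each array left out in turn. The fit was tested on simulated data for 22746 probe sets. In each comparison only 67 of them were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. In the water comparison of the genotypes it recovered 88.1% of 67 probe sets changed 1.5-fold and 100% of 67 changed 2-fold, with 13 false calls. For des1 against wild type under sulfide these shares were 79.1% and 100%, with 6 false calls. For the interaction they were 40.3% and 89.6%, with 9 false calls.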

Results

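The series measured leaf transcripts of Arabidopsis wild type and of an insertion line of DES1, a cytosolic enzyme that breaks down L-cysteine and releases sulfide. Wild type Col-0 and the des1-1 line, which has a T-DNA insertion in DES1, were grown for 20 days and then watered for 10 days with water or with sodium sulfide (Na2S), given as 200 mM in the labels, a dose that is high for plants, that the arrays do not check and that stays uncertain. Leaves came from plants of 30 days, with 3 arrays in each of the 4 groups. The design asks what loss of DES1 does to the leaf transcriptome and whether sulfide supplied from outside changes that difference. The untreated groups had plain water only, so effects of sulfide cannot be told from those of sodium or other properties of the solution. DES1 transcript itself is not analysed here. The series holds a single insertion line and no second allele or rescued line. Differences between the genotypes therefore cannot be told from those of other changes carried by the des1-1 line.

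The untreated genotypes lay farthest apart, and the treated groups lay close together between them. Correlations across probe sets, which are not independent replicates, ran from 0.9451 to 0.9482 between wild type and des1 arrays under water and from 0.9883 to 0.9961 between the genotypes under Na2S. Arrays within a group correlated at 0.9929 to 0.9975. On the first principal component (54.8% of the variance) untreated wild type averaged 55.6 ± 0.603 (SD, n = 3), untreated des1 -59.0 ± 1.77, treated wild type -1.15 ± 0.529 and treated des1 4.53 ± 0.242. The second component (28.7%) set the treated from the untreated groups.

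**Figure D1:**
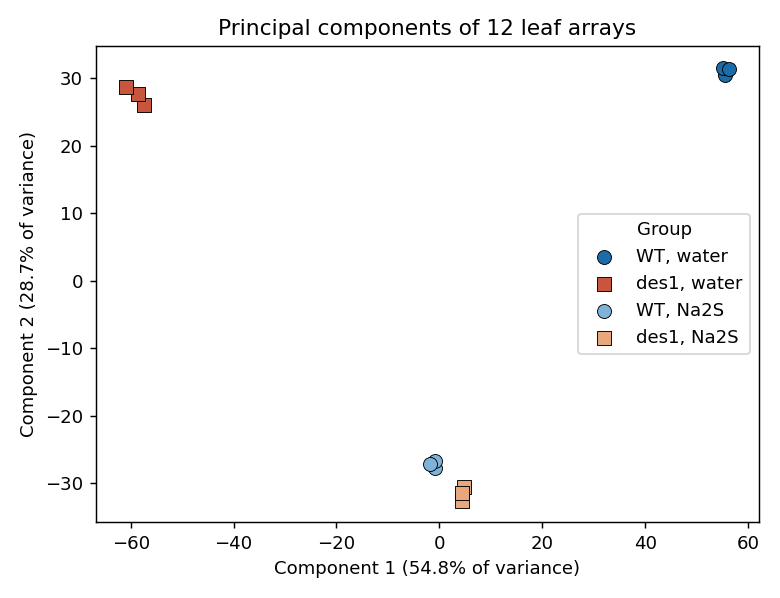
Scores of the 12 arrays on the first 2 principal components of the log2 values (unitless scores, with the percent of variance on each axis), 1 point per array and 1 colour per group. Untreated wild type (mean 55.6) and untreated des1 (mean -59.0) lie at opposite ends of the first component, with both treated groups near 0.

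Under water, loss of DES1 went with a large change of the leaf transcriptome. The cysteine protease gene AT2G27420 rose 71.0-fold in des1 (log2 difference 6.15 ± 0.12 SE, n = 3 per group, limma adjusted p = 1.03e-16), and SAG29, a senescence-associated sugar transporter, rose by 5.93 ± 0.14 on the log2 scale (adjusted p = 1.45e-15). PORB, a light-dependent enzyme of chlorophyll synthesis, fell 84.5-fold (-6.40 ± 0.10, adjusted p = 1.38e-17), and AT1G56300, which encodes a J-domain protein, fell by at least 58.5-fold (-5.87 ± 0.10), to a level below the lower quartile of every array. Further rises were those of AT5G39520 (4.70), AT5G42760 (18.3-fold), AT2G25625 (17.2-fold), the calmodulin-like gene CML41 (4.07), the linker histone HIS1-3 (4.04), AT3G17520 (4.04), AT1G68620 (4.04) and AT3G28270 (4.02). Further falls were those of AT4G29020 (-5.18), AT5G48490 (-5.01), AT2G33850 (-4.76), AT4G30660 (-4.73), AT5G62360 (-4.73), AT5G45670 (-4.72), AT4G30650 (-4.53) and the LIM-domain gene WLIM2a (-4.46).

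The measured flavonoid and anthocyanin genes, 5 of 19 fixed, rose together in untreated des1: all 5 passed the test, and 5 adjusted over the list alone. The other fixed entries, among them CHS, F3H and MYB75, were not used, so a rise of the wider theme was not shown. AT4G14090, an anthocyanin glucosyltransferase, rose by 3.78 ± 0.15, DFR (dihydroflavonol reductase) by 3.64 ± 0.12, UF3GT by 3.26 ± 0.19 and UGT78D2 by 2.35 ± 0.10 on the log2 scale. The list passed camera (adjusted p = 4.86e-06), but not with an estimated correlation (adjusted p = 0.0848 with an estimated correlation). Of 17 autophagy genes 10 rose, 1 fell and 6 did not pass, with the same 10 and 1 adjusted over the list alone. ATG8B rose by 1.24 ± 0.14, APG8A by 0.98 ± 0.12, ATG8G by 0.86 ± 0.13 and AT3G61960 (an ATG1 kinase) by 0.71 ± 0.105, while ATG8E fell (-0.45 ± 0.17). Camera gave adjusted p = 0.013 for autophagy, and adjusted p = 0.353 with an estimated correlation; without dim probe sets camera gave adjusted p = 0.0578. Of 4 senescence genes, out of 23 fixed, 3 rose (3 adjusted over the list alone). They were SAG29, WRKY53 (0.83 ± 0.14) and WRKY6 (0.69 ± 0.14), whereas SAG101 differed by 0.23 ± 0.14 without passing. That list had camera adjusted p = 0.013, and adjusted p = 0.0848 with an estimated correlation. Its mean of 1.92 lay above its median of 0.76 because of SAG29. The other fixed entries were not used, so a rise of the wider senescence theme was not shown.

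The other tested lists did not pass camera under water. Among 7 photosynthesis genes 1 rose and 4 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.161), with LHCB4.1 at -0.64 ± 0.10, PSAN at -0.49 ± 0.105, PSBW at -0.33 ± 0.105 and the Rubisco activase gene RCA at 0.32 ± 0.09. PSBW no longer passed without des1 water replicate 2 (adjusted p = 0.0716). Of 3 glucosinolate genes 2 rose (3 adjusted over the list alone; camera adjusted p = 0.161). The abscisic acid and osmotic list had 2 rises and 1 fall among 4 genes (2 and 2 adjusted over the list alone; camera adjusted p = 0.964); COR15B fell by 2.19 on the log2 scale and COR47 rose by 0.75, and the median of 0.07 and the mean of -0.32 differed in sign. The antioxidant list held 1 rise, glutathione reductase GR1 (2.01 ± 0.11), and 1 fall, the copper chaperone CCS (-1.77 ± 0.11), also adjusted over the list alone (camera adjusted p = 0.964). Of 3 carbon starvation genes 1 rose, 1 adjusted over the list alone (camera adjusted p = 0.964; median -0.15, mean 0.02, test direction down).

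Among sulfur genes measured singly, the cysteine desulfurase gene CPNIFS rose by 0.54 ± 0.125 and the sulfur-deficiency marker AT1G04770 (SDI2) by 0.71 ± 0.10 in untreated des1, while sulfite reductase SIR differed by 0.27 ± 0.11 (limma adjusted p = 0.0558) and BGLU28 by -0.15 ± 0.13 without passing. The defensin genes PDF1.2 (1.77 ± 0.13) and PDF1.2b (1.32 ± 0.21) rose, as did GRX480 (1.34 ± 0.175). Whether the PDF1.2b probe set reads its gene apart from PDF1.2 was not tested, here and under Na2S. Markers of dividing cells fell beside these groups: PRL, a DNA replication factor, by 2.11 and the mitotic kinase AUR1 by 1.83 on the log2 scale. The stomatal lineage genes SPCH (-0.60 ± 0.16) and FMA (-0.34 ± 0.11) fell as well. On the same arrays the 25S rRNA control probe set was lower in des1 (-1.09 ± 0.23, adjusted p = 0.00679) and the ubiquitin control was higher at its 3′ end (0.65 ± 0.09) and its 5′ end (0.91 ± 0.12), in both rescalings too.

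In all, 5015 probe sets were higher and 5151 lower in untreated des1, 10166 of 22746, and 1526 and 1491 of them by at least 2-fold. Those differences rest on 3 arrays per genotype, and the labels give neither a harvest hour nor an array batch or scan date, here and for the Na2S effects.

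Under Na2S the genotypes differed in far fewer transcripts. The defensin genes PDF1.2b (1.69 ± 0.21 SE, n = 3 per group, limma adjusted p = 0.00014) and PDF1.2 (1.57 ± 0.13, adjusted p = 1.17e-06) were higher in treated des1 than in treated wild type, as was AT5G61590, known as DEWAX, a repressor of wax synthesis (1.41 ± 0.145). AT2G20870 was 11.7-fold lower (-3.55 ± 0.15, adjusted p = 1.38e-10) and AT5G22430 was 11.2-fold lower (-3.48 ± 0.16). AT1G62500 (-2.99 ± 0.14, to about the lower quartile of the arrays), AT5G33370 (-2.79 ± 0.16), which encodes a GDSL-family lipase, and AT4G29030 (-2.75 ± 0.21) followed. The other named rises were AT5G19120 (1.27), AT2G23910 (1.25), AT1G70270 (1.12), AT3G55710 (1.00), AT3G28220 (0.95), ATPMEPCRB (0.91) and AT1G04770 (0.90). The other named falls were AT4G23680 (-1.94), AT2G33850 (-1.86), AT1G02813 (-1.61), RXF26 (-1.60) and AT2G28790 (-1.47).

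Several of the genes that moved most under water differed little here. Treated des1 and treated wild type differed by -0.18 ± 0.12 for AT2G27420 (limma adjusted p = 0.621), by -0.09 ± 0.14 for SAG29 (adjusted p = 0.861) and by 0.08 ± 0.10 for PORB (adjusted p = 0.833). AT2G33850 fell in both treatments, whereas CML41 (-0.88), AT2G25625 (-0.78) and AT3G28270 (-0.51), which had risen under water, were lower in treated des1, and AT5G48490 (0.81) and AT4G29020 (0.70) were higher. AT4G29020 lost its call when any array of wild type or des1 Na2S replicate 2 or 3 was left out (adjusted p up to 0.179), and AT3G28270 lost it without des1 Na2S replicate 2 (adjusted p = 0.053) or wild type Na2S replicate 2 (adjusted p = 0.0508).

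No gene list passed camera between the genotypes under Na2S: 0 of 8 lists passed, 0 had an unadjusted p under 0.05, and 0 passed with an estimated correlation or with fry. The lowest camera adjusted p was 0.353, for flavonoid and for senescence genes. Among 17 autophagy genes 0 passed limma, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.48). Of 5 flavonoid genes 1 fell, DFR (-0.50 ± 0.12), and 1 adjusted over the list alone; of the 4 abscisic acid and osmotic genes 1 rose, the dehydrin gene LTI30 (0.79 ± 0.15), 1 adjusted over the list alone (camera adjusted p = 0.58; median -0.04, mean 0.08). Among 4 senescence genes 0 passed limma, 2 had an unadjusted p under 0.05, and 2 were higher adjusted over the list alone. None of the 7 photosynthesis genes (camera adjusted p = 0.472, 0 at an unadjusted p under 0.05), 3 glucosinolate genes (0.472, 0 at that p) and 3 antioxidant genes (0.774, 0 at that p; median below 0, mean 0.01) passed, and 0 adjusted over any of these lists alone. Of 3 carbon starvation genes 0 passed (camera adjusted p = 0.472), with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone.

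Among singly measured genes, the sulfur-deficiency marker AT1G04770 was higher in treated des1, and BGLU28, the other measured gene of that list (-0.12 ± 0.13), CPNIFS (-0.02 ± 0.125), SIR (-0.09 ± 0.11) and GRX480 (0.23 ± 0.175) did not pass. The dividing-cell markers PRL (-0.21 ± 0.11) and AUR1 (-0.28 ± 0.14) did not pass either. Both leaned lower, as under water, and they are only 2 of 17 fixed, so a remaining difference in dividing cells is not excluded. The comparison called 133 probe sets higher and 185 lower, 318 in all, of which 10 and 41 reached 2-fold; 2586 had an unadjusted p under 0.05. The count was 186 without wild type Na2S replicate 2, 189 without des1 Na2S replicate 1, 198 without des1 Na2S replicate 2, 205 without wild type Na2S replicate 1 and 207 without des1 Na2S replicate 3, and 838 with array weights.

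The Na2S effect in wild type asks how leaves with DES1 respond to the Na2S solution. AT2G27420 rose 61.7-fold (5.95 ± 0.12 SE, n = 3 per group, limma adjusted p = 2.77e-16), and HYH, a bZIP factor of light responses, rose by 3.71 ± 0.13 on the log2 scale. AT1G56300 fell by at least 63.7-fold, again to below that quartile (-5.99 ± 0.10, adjusted p = 1.77e-17) and PORB fell 30.9-fold (-4.95 ± 0.10). Further rises were AT5G42760 (3.71), AT5G47610 (3.57), TBL26 (3.51), the chalcone isomerase-like gene CHIL (3.38), AT3G28270 (3.32), AT5G54130 (3.18), the jasmonate methyltransferase gene JMT (3.12) and AT3G15310 (3.08). Further falls were AT3G62550 (-4.99), AT5G62360 (-4.84), AT3G47160 (-4.75), AT4G30660 (-4.74), AT2G39920 (-4.69), AT4G16146 (-4.26), CCL (-3.90) and DPE1, a plastid enzyme of starch breakdown (-3.88).

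The measured abscisic acid and osmotic genes, 4 of 28 fixed, fell in treated wild type: all 4 passed, and 4 adjusted over the list alone. COR15B stood at -2.29 ± 0.125, LTI30 at -1.68 ± 0.15, COR15A at -0.97 ± 0.17 and COR47 at -0.57 ± 0.12. The other fixed entries, among them RD29B, RAB18 and NCED3, were not used, so a fall of the wider theme was not shown. The list passed camera (adjusted p = 0.000355), and also passed with an estimated correlation (adjusted p = 0.0298 with an estimated correlation). Of 17 autophagy genes 5 fell and 12 did not pass (6 fell adjusted over the list alone), led by ATG8E (-1.16 ± 0.17), ATG8D (-1.03 ± 0.15) and ATG8F (-0.75 ± 0.11). Camera gave adjusted p = 0.0127 for autophagy, adjusted p = 0.246 with an estimated correlation, and adjusted p = 0.0581 without dim probe sets. Of 3 antioxidant genes 2 rose (2 adjusted over the list alone), GR1 (1.58 ± 0.11) and CCS (0.64 ± 0.11); camera gave adjusted p = 0.0342, adjusted p = 0.114 with an estimated correlation, and adjusted p = 0.0573 without wild type water replicate 1. Of 3 carbon starvation genes 2 fell (2 adjusted over the list alone), AT1G03090 (MCCA) at -0.87 ± 0.11 and AKINBETA1 at -0.82 ± 0.115, with camera adjusted p = 0.0276, adjusted p = 0.114 with an estimated correlation, and adjusted p = 0.0699 without dim probe sets.

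The remaining lists did not pass camera in wild type. Among 5 flavonoid genes 1 rose and 2 fell, also adjusted over the list alone: UGT78D2 rose by 2.21, DFR fell by 1.26 and UF3GT fell by 0.54 on the log2 scale (camera adjusted p = 0.756; median -0.23, mean 0.04). UF3GT lost its call in both rescalings and when single arrays were left out, at most with adjusted p = 0.207 without wild type Na2S replicate 1. Senescence genes went both ways, with SAG29 2.47-fold higher and WRKY53 at -0.38 (1 and 1 adjusted over the list alone; camera adjusted p = 0.841; median -0.27, mean 0.10). Of 7 photosynthesis genes 0 passed limma, 1 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone (camera adjusted p = 0.555). Among 3 glucosinolate genes 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.683). Among single genes, SIR (0.57 ± 0.11) and CPNIFS (0.44 ± 0.125) rose, the iron-deficiency regulator BHLH101 fell (-2.08 ± 0.12), the clock gene GI fell (-1.61 ± 0.12) and the dividing-cell marker PRL fell (-0.98 ± 0.11), while AUR1 did not pass (-0.33 ± 0.14).

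In wild type 3409 probe sets were higher and 3510 lower with Na2S, 6919 in all, of which 712 and 777 reached 2-fold. With arrays centred on their medians the split was 4106 higher and 3061 lower, so the larger side depends on the scaling.

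The Na2S effect in des1 asks how leaves without DES1 respond. DFR fell by at least 42.1-fold, to about the lower quartile of the arrays (-5.40 ± 0.12 SE, n = 3 per group, limma adjusted p = 1.38e-15), AT5G39520 fell 40.8-fold (-5.35 ± 0.14) and SAG29 fell 26.3-fold (-4.72 ± 0.14). AT5G48490, a lipid transfer protein gene, rose 49.1-fold (5.62 ± 0.11, adjusted p = 5.68e-16) and AT4G29020 rose 31.6-fold (4.98 ± 0.16). Further rises were AT5G45670 (4.40), AT1G11850 (3.86), AT3G16670 (3.86), AT3G05730 (3.73), AT4G28780 (3.60), the cell wall enzyme gene XTH16 (3.44), AT3G54400 (3.43) and AT5G62210 (3.42). Further falls were the putative chitinase gene CHI (AT2G43570, -4.53), AT3G13672 (-4.31), HIS1-3 (-4.10), AT3G17520 (-4.05), UF3GT (-4.04), AT2G25625 (-3.96) and AT1G68620 (-3.93).

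Autophagy genes fell as a group in treated des1: 16 of 17 fell, the same number adjusted over the list alone, with ATG8G at -1.33 ± 0.13, ATG8B at -1.27 ± 0.14 and APG8A at -1.21 ± 0.12. The probe set with the higher mean was used for AT2G37840 (ATG1C, -0.65), and its other probe set differed by -0.02. Flavonoid genes fell in 4 of 5 cases (4 adjusted over the list alone), including AT4G14090 (-3.83 ± 0.15) beside DFR and UF3GT, and UGT78D2 differed by -0.19 ± 0.10. All 4 senescence genes fell (4 adjusted over the list alone), with WRKY53 at -0.67 ± 0.14 and SAG101 at -0.63 ± 0.14. The abscisic acid and osmotic list had 3 falls among 4 genes (3 adjusted over the list alone), LTI30 (-1.43 ± 0.15), COR47 (-1.24 ± 0.12) and COR15A (-0.95 ± 0.17). All 3 carbon starvation genes fell (3 adjusted over the list alone), with AT3G45300 (IVD) at -0.92 ± 0.12. Camera gave adjusted p = 7.12e-08 for autophagy, 1.22e-06 for flavonoid, 0.0019 for senescence, 0.00382 for abscisic acid and osmotic and 0.00791 for carbon starvation genes. These 5 lists also passed with an estimated correlation (adjusted p = 0.0323 for the first 4 and adjusted p = 0.035 for carbon starvation, with an estimated correlation).

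The other 3 lists did not pass camera in des1. Of 7 photosynthesis genes 2 rose (2 adjusted over the list alone), PSAN (0.53 ± 0.105) and LHCB4.1 (0.45 ± 0.10), with camera adjusted p = 0.124. The antioxidant list held 1 rise, CCS (2.57 ± 0.11), and 1 fall, GR1 (-0.43 ± 0.11), also adjusted over the list alone (camera adjusted p = 0.505; median -0.14, mean 0.67). Of 3 glucosinolate genes 1 fell, BCAT4 (-0.73 ± 0.10), 1 adjusted over the list alone (camera adjusted p = 0.164). The dividing-cell markers AUR1 (1.22 ± 0.14) and PRL (0.92 ± 0.11) rose beside these groups, as did the stomatal lineage genes SPCH (0.61 ± 0.16) and FMA (0.59 ± 0.11). On the same arrays the 25S rRNA control rose (0.96 ± 0.23, limma adjusted p = 0.0171), and the ubiquitin control fell at its 3′ end (-0.64 ± 0.09) and its 5′ end (-0.62 ± 0.12). The actin control fell at its 3′ end (-0.33 ± 0.08, adjusted p = 0.0194), but not with arrays centred on their medians (adjusted p = 0.0512). Among sulfur genes, CPNIFS (-0.12 ± 0.125), SIR (0.21 ± 0.11) and AT1G04770 (-0.04 ± 0.10) did not pass.

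In des1 3989 probe sets were higher and 4454 lower with Na2S, 8443 in all, of which 785 and 933 reached 2-fold. The excess of lower ones was not kept by scaling, with 4425 higher and 4072 lower after median centring and 4159 and 4168 after quantile normalization again. Across probe sets, which are not independent, the Na2S effects in wild type and in des1, which share no arrays, correlated at r = -0.0477. Both effects were called higher for 734 probe sets (598 by independence) and lower for 952 (687), while 1167 were higher in wild type and lower in des1 (668) and 1062 were lower in wild type and higher in des1 (616).

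**Figure D2:**
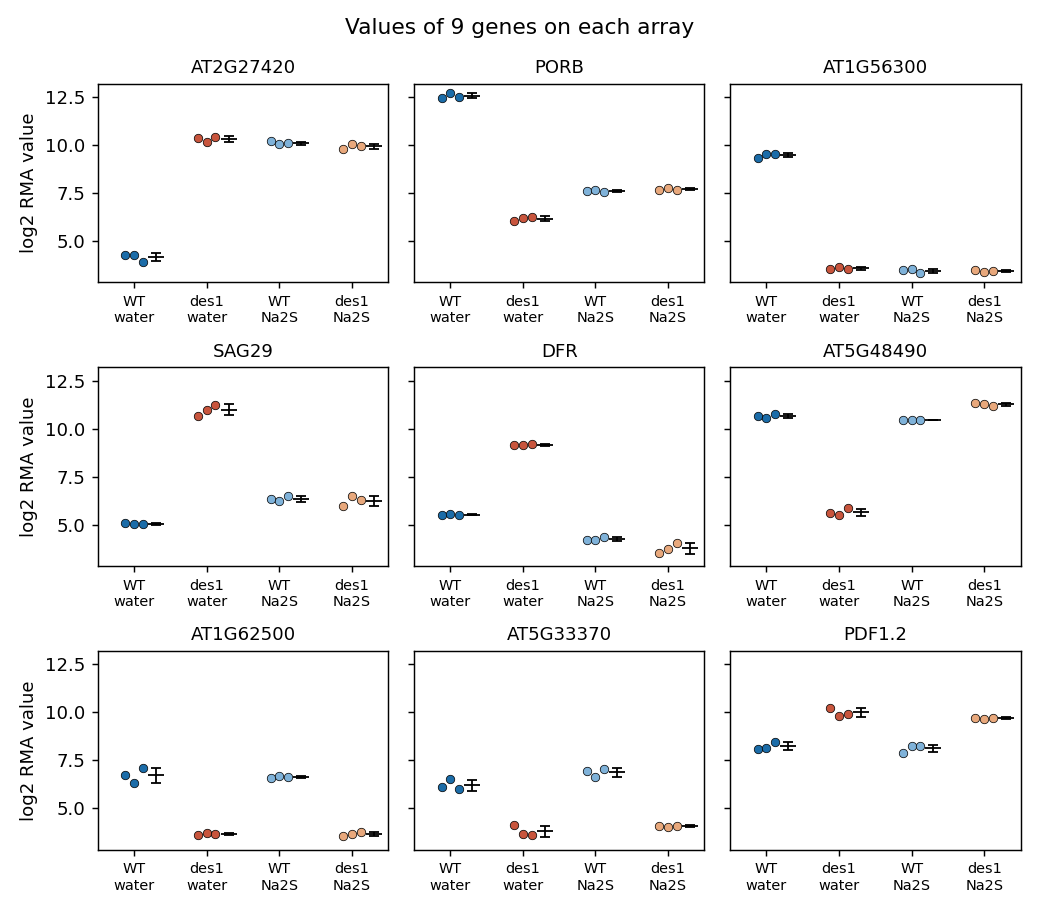
Log2 expression of 9 genes on each array (points) with group means and SD (bars, n = 3), chosen after their values were seen from genes the naming rule gives. PORB lies between 12.44 and 12.71 on the untreated wild type arrays and between 7.55 and 7.73 on the treated arrays.

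The genotype difference itself changed with Na2S for a large part of the transcriptome. The interaction, positive where des1 minus wild type was larger under Na2S than under water, was 6.48 ± 0.14 for PORB (limma adjusted p = 6.6e-15), 5.88 ± 0.23 for AT4G29020, 5.85 ± 0.14 for AT1G56300, 5.82 ± 0.15 for AT5G48490 and 5.03 ± 0.165 for AT5G45670. It was -6.33 ± 0.17 for AT2G27420 (adjusted p = 1.78e-14), -6.02 ± 0.20 for SAG29, -5.17 ± 0.20 for AT5G39520, -5.04 ± 0.16 for CHI and -5.03 ± 0.18 for AT4G23680. The way in which the difference closed varied between genes. PORB averaged 12.55 ± 0.14 (SD, n = 3) in untreated wild type and 6.15 ± 0.12 in untreated des1, and treated wild type (7.60 ± 0.05) and treated des1 (7.68 ± 0.05) lay between them, after a fall of 4.95 in wild type and a rise of 1.53 in des1 on the log2 scale. SAG29 averaged 10.97 ± 0.29 in untreated des1 and 5.04 ± 0.05 in untreated wild type, and treated des1 (6.25 ± 0.26) and treated wild type (6.34 ± 0.15) lay between them, after a fall of 4.72 in des1 and a 2.47-fold rise in wild type.

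All 5 flavonoid genes had a negative interaction (5 adjusted over the list alone; camera adjusted p = 2.23e-06, adjusted p = 0.127 with an estimated correlation), with DFR at -4.14 ± 0.17 and AT4G14090 at -3.86 ± 0.215. Of 17 autophagy genes 8 were negative and 1 positive (8 and 1 adjusted over the list alone), led by ATG8B (-1.35 ± 0.19) and ATG8G (-1.24 ± 0.18). Camera gave adjusted p = 0.0246 for autophagy, adjusted p = 0.375 with an estimated correlation, 0.0728 without dim probe sets and 0.0779 without des1 Na2S replicate 2. The other lists did not pass. Senescence had 1 negative member (1 adjusted over the list alone; camera adjusted p = 0.0775, and 0.0438 without wild type Na2S replicate 1). Glucosinolate genes had 3 negative of 3 (3 adjusted over the list alone; camera adjusted p = 0.137), and photosynthesis genes 3 positive of 7 (4 adjusted over the list alone; camera adjusted p = 0.137). Abscisic acid and osmotic genes had 1 positive and 1 negative of 4 (camera adjusted p = 0.624), and antioxidant genes 1 and 1 of 3 (camera adjusted p = 0.85), with equal counts adjusted over each list alone. Carbon starvation had 1 negative of 3 (1 adjusted over the list alone; camera adjusted p = 0.85; median 0.10, mean -0.14). Beside these lists the dividing-cell markers PRL (1.90 ± 0.16) and AUR1 (1.55 ± 0.195) had positive interactions. So did the 25S rRNA control (1.22, limma adjusted p = 0.0426), and the ubiquitin control had negative ones at its 3′ end (-0.76, adjusted p = 0.00268) and its 5′ end (-1.02, adjusted p = 0.00251). Calls of PSBW, BCAT4 and UGT74B1 were lost when single arrays were left out, with adjusted p up to 0.0662 without des1 Na2S replicate 1, up to 0.0683 without wild type water replicate 2 and 0.071 without wild type Na2S replicate 2.

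The interaction was called for 8573 probe sets, 4232 positive and 4341 negative. Of the 10166 probe sets that differed between genotypes under water, 9891 were not called under Na2S, 93 were called the same way and 182 the opposite way, and 8166 (80.3%) passed the interaction against their direction under water. Na2S moved des1 back in 6086 (59.9%) and moved wild type toward the untreated des1 level in 5020 (49.4%); 2228 did both and 1288 neither. Of the 3017 that differed at least 2-fold under water, 2998 (99.4%) passed the interaction against their direction, des1 moved back in 2306 (76.4%), wild type moved in 2243 (74.3%) and both in 1545 (51.2%). The median difference, signed by its direction under water, was 0.69 under water and -0.05 under Na2S. In simulated arrays with the same genotype difference in both treatments and no Na2S effect, a comparison chosen after the data were seen, 9582 of 11264 probe sets were called the same way, 4 the opposite way, and 0 passed the interaction against their direction. Across probe sets, which are not independent, the genotype differences under water and under Na2S correlated at r = -0.178 (Spearman -0.211), against 0.974 in that simulation. Of the 133 probe sets higher in des1 under Na2S, 104 were lower under water, where independent lists would share 30.1 (Fisher's exact test p = 4.33e-42), and 13 were higher under both, where 29.3 would be shared (p = 0.000315). Of the 185 lower ones, 78 were higher under water (40.8 by independence, Fisher's exact test p = 1e-09) and 80 were lower (41.9 by independence, Fisher's exact test p = 4.66e-10). The excess was thus not confined to opposite directions. Fisher's test takes probe sets as independent, which they are not, and includes dim ones that can hardly be called in either comparison. Its p-values therefore measure no spread between plants.

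The genotype difference under water and the Na2S effect in wild type correlated at r = 0.707, with a covariance of 0.295, but share the untreated wild type arrays. With all arrays simulated as noise without group differences, the same sharing gave r = 0.492 and a covariance of 0.00767. The real effects shared 2428 probe sets higher in both (752 by independence) and 2592 lower in both (795). The noise arrays gave 0 calls in the same direction. Without group differences hardly any probe set passes, so that count could not show an effect of sharing. Part of the real excess may come from the shared arrays. But sharing alone gave a covariance of 0.00767 beside the real 0.295, so r = 0.492 does not mean that sharing makes most of the real correlation. The genotype difference under water and the Na2S effect in des1, which share the untreated des1 arrays, correlated at r = -0.702 with a covariance of -0.31, against -0.498 and -0.00775 in the simulation.

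Treated des1 was not back at the untreated wild type level. PORB (7.68 ± 0.05 against 12.55 ± 0.14, SD, n = 3) and AT1G56300 (3.43 ± 0.03 against 9.44 ± 0.10) lay lower and AT2G27420 (9.91 ± 0.13 against 4.14 ± 0.21) higher in treated des1. In limma 3229 probe sets were higher and 3654 lower, 6883 in all, of which 1475 reached 2-fold. With arrays centred on their medians the split was 4080 higher and 3076 lower, so the larger side depends on the scaling. Of the 10166 probe sets called under water, 4648 (45.7%) still differed between treated des1 and untreated wild type, as did 2124 (70.4%) of the 3017 at 2-fold or more. These share arrays: the correlation of both differences was 0.649 (covariance 0.269), against 0.502 (0.00784) for simulated unchanged groups.

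**Figure D3:**
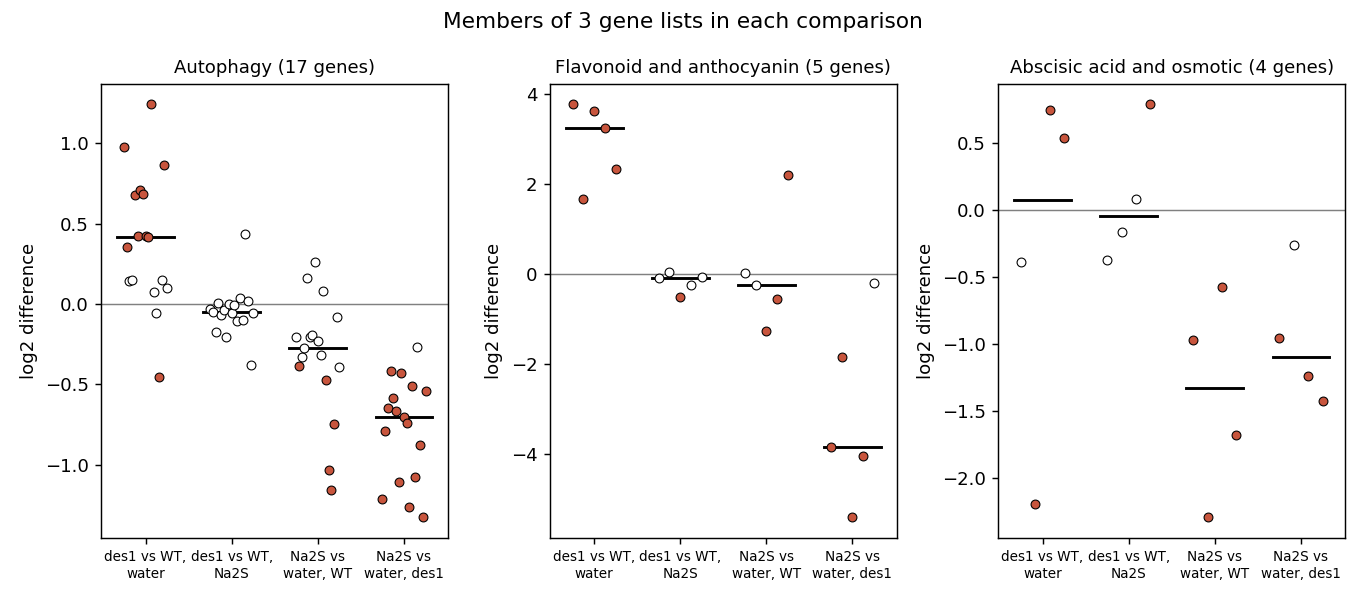
Log2 differences (y axis) of the members of 3 gene lists in 4 comparisons, 1 point per gene, with filled points past limma's adjusted p of 0.05 and a line at the list's median. Under water the flavonoid median was 3.26 and the autophagy median 0.42, and with Na2S in des1 they were -3.83 and -0.70.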

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

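The tests of RNA degradation, of young leaves, of exchanged labels and of other splits of the arrays were chosen only after the results they bear on were seen; the bounds for the harvest hour were written before its value.

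The genotype difference was not the same under water and under Na2S, by limma's interaction, for 8573 probe sets, with no explanation tested for single genes. Positive interactions were those of PORB (6.48), AT4G29020 (5.88), AT1G56300 (5.85), AT5G48490 (5.82) and AT5G45670 (5.03), and negative ones those of AT2G27420 (-6.33), SAG29 (-6.02), AT5G39520 (-5.17), CHI (-5.04) and AT4G23680 (-5.03). The flavonoid list differed between treatments (camera adjusted p = 2.23e-06, but adjusted p = 0.127 with an estimated correlation), through DFR (-4.14), AT4G14090 (-3.86), UF3GT (-3.50) and UGT78D2 (-2.40). The autophagy list did too (camera adjusted p = 0.0246), through ATG8B (-1.35), ATG8G (-1.24), APG8A (-1.01) and AT3G61960 (-0.92). That autophagy call was lost with an estimated correlation (adjusted p = 0.375), without dim probe sets (0.0728) and without des1 Na2S replicate 2 (0.0779). Members of lists that did not pass camera also differed: AT2G31790 (-0.67), UGT74B1 (-0.42) and BCAT4 (-0.39) among glucosinolate genes, and LHCB4.1 (0.60), PSAN (0.57) and PSBW (0.46) among photosynthesis genes. Control probe sets, which the lists do not cover, also differed in limma: ubiquitin at its 3′ end (0.647) and 5′ end (0.91) in des1 under water, and 25S rRNA (0.963) with Na2S in des1.

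Untreated wild type stood apart from the other 3 groups, with 2191 probe sets higher and 1971 lower than in all of them. Harvest at another hour may contribute: the morning gene CDF5 differed from the mean of the other groups by -1.60 and the evening gene GI by 1.46, the directions that explanation needs. The evening median over 3 genes was 0.183, which met neither bound. But it is the value of COR28, which like COR27 (-0.07) lay below the lower quartile of every array and can hardly show a shift. CDF5 was the only morning gene of 15 listed that was used. The others had no matched probe set in the annotation used here, which does not mean that the arrays lack them. More degraded RNA in these samples was not detectable, since 3′ minus 5′ values of control genes differed by 0.0344 from the other arrays (exact permutation p = 0.691, two-sided), less than their SD of 0.13; this does not exclude it. A response of wild type to sulfide, which the design names, stays open as untested against these.

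Untreated des1 stood apart as well, with 2688 probe sets higher and 2526 lower than in all 3 other groups. Fewer young leaves in these samples is a candidate explanation: the dividing-cell markers PRL (-1.39) and AUR1 (-1.52) had a median of -1.45 below the other groups, each lower than in every other group in limma. Those are only 2 genes of 17 fixed, and slower growth or earlier ageing of the mutant leaf would lower them too, so the explanation stays open and was not told from an effect of genotype. RNA degradation differed by 0.073 in the 3′ minus 5′ values (exact permutation p = 0.405, two-sided), within the SD of 0.13, which leaves it open. The lower 25S rRNA control (-1.09) and the higher ubiquitin control were not explained.

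Genotype differences under Na2S ran against those under water more often than independent lists would share, 182 of the 275 probe sets called in both (66.2%). Probe sets lower in both treatments were in excess too (80, against 41.9 by independence). Exchanged genotype labels within 1 treatment may give the opposite calls. But among the 35 probe sets at 2-fold or more in both treatments 31.4% changed sign and 24 kept it, including AT1G62500 and AT5G33370. Exchanged labels would turn most of these around, unless the true differences were opposite, and a value between the bounds set for the test leaves it open. DES1 transcript, which would check the labels, is not analysed here. An effect of sulfide that overshoots in des1 stays open as untested.

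The counts were also taken for other splits of the arrays. For each comparison of 3 against 3 arrays the 10 splits are too few for a share under 0.05. Each other split also mixes arrays of the compared groups, which adds their difference to the spread and pushes its count toward 0. Low counts of probe sets in those splits therefore do not tell against chance. The real counts were 10166 for the genotypes under water, 318 under Na2S, 6919 for Na2S in wild type, 8443 in des1 and 6883 for treated des1 against untreated wild type, and the highest other split gave 0 each time. For gene lists past camera the real numbers in the first 4 of these were 3, 0, 4 and 5, and the highest others were 4, 2, 2 and 4; splits with as many numbered 2, 10, 1 and 1 of 10. For the interaction 1 of 100 drawn splits, the real one, gave 8573 probe sets and the highest other gave 8211. The splits with over 50% of the real count numbered 11, the real one included, and all 11 kept the untreated arrays parted by genotype. That parting, for which the splits are too few for a share under 0.05, sets the count, so the 100 splits do not decide. For its gene lists 14 of 100 splits gave as many as the real 2 (highest other 3), so chance is not excluded there.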

How the results depend on the processing

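Comparing with simulated arrays was chosen after the data were seen; the other alternatives were set before. Quantile normalization again, median centring, the trended robust model and the fit to the compared arrays alone moved no count of probe sets by over 1.5 times. A 2-fold minimum left 3017 probe sets (genotypes, water), 51 (genotypes, Na2S), 1489 (Na2S, wild type), 1718 (Na2S, des1), 3426 (interaction) and 1475 (treated des1 against untreated wild type); with 2-fold asked in the second comparison too, of those called under water 24 kept their way under Na2S, 2813 had the interaction against them, 1162 moved back in des1, 1098 moved toward des1 in wild type and 1025 still differed. With probe sets of 1 gene only, which tests fewer of them, these were 5397, 134, 3526, 4442, 4472 and 3598, then 50, 4245, 3169, 2519 and 2388. Array weights gave 838 for the genotypes under Na2S and 199 called the same way in both treatments; the cause was not tested. Lists past camera without dim probe sets numbered 1 (genotypes, water), 1 (Na2S, wild type) and 1 (interaction). Senescence (water) and antioxidants (wild type) fell out because under 3 members were left, while autophagy (0.0578, 0.0581 and 0.0728) and, in wild type, carbon starvation (0.0699) were tested and did not pass, for which the cause was not tested. With an estimated correlation they numbered 0, 1 and 0. Fry, which asks another question, gave 6 (directional) and 6 (mixed) for the genotypes under water, 8 (mixed) for Na2S in wild type, 8 and 8 in des1, and 6 and 6 for the interaction. Leaving out single arrays gave 9350 to 10436, 186 to 357, 5979 to 7160, 7432 to 8749, 7937 to 8571 and 5985 to 7185 for the counts in the order above. Of probe sets called under water, 58 to 98 kept their way, 7525 to 8080 had the interaction against them, 5345 to 6284 moved back in des1, 4428 to 5045 moved in wild type and 4106 to 4832 still differed; the median signed difference was -0.05 throughout and the correlation of both genotype differences -0.197 to -0.145. The genotype count under Na2S moved by over 1.5 times without wild type Na2S replicate 2 (186) or 1 (205) and des1 Na2S replicate 1 (189), 2 (198) or 3 (207), and the same-way count without wild type Na2S replicate 2 (58); the cause was not tested. Lists past camera ranged 3 to 3 and 0 to 0 for the genotypes, 3 to 4 for Na2S in wild type (3 without wild type water replicate 1), 5 to 5 in des1 and 1 to 3 for the interaction (1 without des1 Na2S replicate 2, 3 without wild type Na2S replicate 1). With the replicate number as a block the counts were 10025, 274, 6728, 8235, 8401 and 6698, and the block changed no list. The numbers do not pair the arrays: 1 of 18 pairs of same-numbered arrays had a correlation of deviations over 0.1 (-0.215 to 0.162), and 1 of 12 arrays correlated best with its own number. Over named genes, 3168 of 3238 recomputed values stayed past the test in the same direction, 70 no longer passed and 0 reversed; 114 of 156 gene results held under every alternative. Alternatives set for DES1 were not run, because no probe set is paired with it here. Dim probe sets limit what can be seen: the lower quartile of each array lay at 3.69 to 3.90.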

Other observations

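Of 18 expansin genes, whose products loosen the growing cell wall, 8 fell in untreated des1, 0 rose and 10 did not pass, with EXPA8 at -3.18 ± 0.11 (SE, n = 3 per group), EXPB1 at -2.79 ± 0.11, EXPB3 at -1.86 ± 0.12 and EXPA15 at -1.72 ± 0.12. The family had limma camera adjusted p = 0.00174, and adjusted p = 0.395 with an estimated correlation. With Na2S in des1 9 of 18 rose, led by EXPB1 (3.30 ± 0.11) and EXLA2 (2.32 ± 0.13), with camera adjusted p = 9.32e-05 and adjusted p = 0.249 with an estimated correlation. The dividing-cell markers PRL (-2.11 under water, 0.92 with Na2S in des1) and AUR1 (-1.83 and 1.22) likewise fell in untreated des1 and rose with Na2S in des1. So did the 25S rRNA control (-1.09 and 0.96), while the ubiquitin control went the other way at its 3′ end (0.65 and -0.64). The interaction was positive for 9 (camera adjusted p = 0.00245, and 0.462 with an estimated correlation). The families were formed after the data were seen, 34 were tested in each comparison, and these directions held under both rescalings.

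Signals of probe sets for the 2 organelle genomes moved apart in untreated des1. Whether these signals follow the level of organelle RNA was not tested. Of 23 probe sets of mitochondrial genes 13 rose and 0 fell, among them ccb452 (1.45 ± 0.10) and cox1 (0.99 ± 0.18), with camera adjusted p = 0.00174 and adjusted p = 0.0843 with an estimated correlation. Of 69 probe sets of plastid genes 23 fell, among them psbB (-1.33 ± 0.18), and 2 rose, psbI and psbK, with camera adjusted p = 0.0228 and adjusted p = 0.652 with an estimated correlation. With Na2S in des1 12 mitochondrial probe sets fell (camera adjusted p = 0.00428, and 0.149 with an estimated correlation), and in wild type 13 plastid probe sets fell and 1 rose (0.0395, and 0.96 with an estimated correlation). The other pairings with Na2S did not pass: plastid probe sets in des1 had 9 rises and 6 falls (camera adjusted p = 0.864), and mitochondrial ones in wild type 6 rises and 0 falls (0.396). The interaction was negative for 12 mitochondrial probe sets and positive for 0 (camera adjusted p = 0.00609, and 0.146 with an estimated correlation). For plastid probe sets it was positive for 9 and negative for 2 (0.134). These were also chosen after the data were seen, and several probe sets can belong to 1 organelle gene. On the same arrays of untreated des1 PRL (-2.11), AUR1 (-1.83) and the 25S rRNA control (-1.09, adjusted p = 0.00679) were lower, and the ubiquitin control was higher at its 3′ end (0.65) and its 5′ end (0.91). With Na2S in des1 PRL (0.92), AUR1 (1.22) and 25S rRNA (0.96) rose and ubiquitin fell at its 3′ end (-0.64).

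A small group of probe sets differed by genotype in the same direction in both treatments, 13 higher and 80 lower in des1. AT1G62500 fell by at least 3.05 under water and by at least 2.99 under Na2S on the log2 scale. Its des1 values lay at about the lower quartile of the arrays in both treatments, so the similar sizes are not a measured equality. AT4G29030 fell by 3.74 and 2.75, and AT5G33370 by 2.39 and 2.79. Unnamed probe sets fell too, 2 of them by -5.20 and -2.45, and by -2.42 and -3.40. PDF1.2 rose by 1.77 and 1.57, AT1G04770 by 0.71 and 0.90, BHLH101 by 1.37 and 0.54 and QQS by 1.31 and 0.61. Several of these were singled out after their values were seen.

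Genes measured singly gave further values, in limma with n = 3 per group. The iron-deficiency regulators BHLH101 (-2.08 and -2.91) and PYE (-0.35 and -1.36) fell with Na2S in wild type and in des1, and the zinc finger gene STZ fell by 1.81 and 1.74. BZIP60, a regulator of the unfolded protein response, rose in untreated des1 (0.93) and with Na2S in wild type (0.68), and fell with Na2S in des1 (-0.41). The trichome regulator TRY rose in untreated des1 (1.78), with Na2S in wild type (2.70) and in des1 (0.64). AT5G06700, the other measured gene of the trichome list, fell in untreated des1 (-0.39) and rose with Na2S in des1 (0.49). The root genes EXPA7 and EXPA18 passed in no comparison, with 0.30 ± 0.13 the highest value, for EXPA7 with Na2S in des1.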
